A study of Mus musculus with 6 samples.

How the data were processed

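RNA was sequenced from mouse splenic CD4+ T cells that had been differentiated in culture towards the Th17 fate and then sorted as EGFP+ cells, where EGFP reports transcription from the Il17a locus. Per the labels' protocols, cells were stimulated overnight with 0.25 µg/mL anti-CD3 and 1 µg/mL anti-CD28, and were polarised with TGF-beta at 2 ng/mL and IL-6 and IL-23 at 20 ng/mL each, with antibodies blocking IL-4 and IFN-gamma at 2 µg/mL each. The 6 libraries were grouped by the genotype in their labels into 3 WT and 3 K256R libraries, and the labels call the replicates biological.

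The authors deposited 1 table of CPM (read counts scaled to the same total in each library) with 16798 genes and 6 sample columns, all of which were used. Per the submitters' processing notes, Partek (version 9.0.20.0629) and STAR were used with GRCm38/mm10. The notes give neither the role of each tool nor the annotation or the strand setting. In the deposited CPM table every value carries an offset of 0.0001, which was subtracted. Each gene of the table had at least 16 reads summed over the 6 libraries. The lowest values fell on steps of a single read, from which the assigned reads per library came to 15.8 to 20.064 M. Of the values below 20 reads, 78.4 to 80.1% per library lay within 0.02 of a whole read. The rest were fractional, as for reads shared between features, so that the table was treated as CPM and no count model was used as the main test. One read corresponded to 0.0498 to 0.0633 CPM, and 3 reads to 0.1495 to 0.1899 CPM. Such floors cover counting error only. Coordinates are those of the table on GRCm38, written from 1 with both ends included. Of the symbols, 16406 were found in GENCODE release M21, and 16243 of these had identical coordinates.

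Differences between genotypes were tested with limma 3.58.1 in R 4.3.3 on log2(CPM + 1), with eBayes using its trend and robust options, over the 13224 genes with a mean CPM of at least 1. The test was two-sided, genotype was its single term, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. It assumed for each gene a common variance in both groups. Log2 differences are K256R minus WT on the log2(CPM + 1) scale, which understates the change of low genes. Gene lists were tested with camera at a preset inter-gene correlation of 0.01, with adjustment over 30 lists, and again with an estimated correlation and with fry. Camera compares the members of a list with all other tested genes. Lists of cell markers, and lists added after the data had been seen, were not among the 30. Their camera p-values were adjusted within each of these kinds of list. The lists, the test, the main alternatives and the rule for naming genes were fixed before the data were examined. Camera on the marker lists was not in that plan, which set only their values and counts of members past the test. Named genes are Il17a, the 12 largest rises and 12 largest falls among genes past the threshold with a mean CPM of at least 5 and no overlap between the groups, the members with the smallest p of each list, and members of the Th17 lists. Unnamed gene models, immunoglobulin and T cell receptor variable segments, pseudogenes and sex-linked genes were left out of the largest rises and falls. Some genes that the rule takes, and a test that rests on their position, are not reported here. Genes outside that rule are said to be chosen after their values were seen.

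The test was tried on simulated data for the same comparison, drawn from the real means and depths with a negative binomial dispersion of 0.0153. Over 13206 simulated genes, 58.2% of the 67 genes changed 1.5-fold were recovered, 97.0% of the 67 changed 2-fold and 100% of the 66 changed 4-fold, with 4 false calls. Every simulated gene had the same dispersion in both groups, and no simulated library stood apart. The real K256R libraries differed more among themselves than the WT libraries, so recovery in the real comparison may be lower. The alternatives were a pseudocount of 0.1, no filter, a minimum mean of 5 CPM, median-of-ratios scaling, eBayes without trend or robust options, the replicate number as a block, and leaving out each library in turn. Precision weights from voom on the recovered reads, and removal of each library's trend on GC content and transcript length, were added after the data had been seen. No 2 libraries of a group agreed within sampling noise: chi-square per gene was 10.0 to 13.6 between WT libraries and 36.8 to 73.8 between K256R libraries.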

Results

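Transcriptomes were measured in EGFP+ cells sorted from Th17 cultures of mouse splenic CD4+ T cells, with 3 libraries from WT and 3 from RORγt-K256R mice that both carried the Il17a-EGFP reporter. RORγt is the nuclear receptor that directs Th17 differentiation, and K256R replaces a lysine of the protein by arginine. The comparison asks how cells that switched on the Il17a reporter differ between the genotypes, in a study concerned with the separate roles of RORγt in Th17 differentiation and effector function. Each library held 15.8 to 20.064 M assigned reads.

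Il17a (chromosome 1, 20730905 to 20734496, GRCm38), the gene whose reporter defined the gate, stood at 850, 1035 and 815 CPM in WT replicates 1 to 3 and at 299, 376 and 571 CPM in K256R replicates 1 to 3. Its mean of 900 ± 118 CPM in WT against 415 ± 140 CPM in K256R (SD, n = 3) gave a log2 difference of -1.16 (SE 0.22) that did not pass over all genes, with an adjusted p of 0.0507 in limma. It passed when adjusted over the list alone among RORγt-dependent genes (adjusted p = 0.0023), in limma without the filter on low values (adjusted p = 0.0447) and without K256R replicate 1 (adjusted p = 0.0142) or K256R replicate 3 (adjusted p = 0.0217). It did not pass in limma without K256R replicate 2 (adjusted p = 0.129) or when any 1 WT library was left out (adjusted p of 0.168 to 0.219).

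Il22, an epithelium-directed cytokine of Th17 cells, fell most on the log2(CPM + 1) scale among all genes past the threshold. Its level (chromosome 10, 118204942 to 118210047) was 446 ± 106 CPM in WT and 69.5 ± 34.0 CPM in K256R (SD, n = 3), a log2 difference of -2.74 (SE 0.32, limma adjusted p = 0.0158). It did not pass when any 1 WT library was left out (adjusted p of 0.0773 to 0.117 in limma), but at most 3 genes of all passed in those fits. In 11 of 14 settings it kept its call. Il23r, which encodes the receptor subunit for IL-23, fell from 39.96 ± 6.31 to 19.3 ± 3.74 CPM (log2 difference -1.02, adjusted p = 0.0438 in limma), and lost its call in 8 of 14 settings, among them each fit without 1 WT library (adjusted p of 0.133 to 0.202) and those without K256R replicate 2 (adjusted p = 0.07) or K256R replicate 3 (adjusted p = 0.0774). Furin, a proprotein convertase, fell from 1115 ± 41.8 to 544 ± 113 CPM (log2 difference -1.06). Il17f was the most abundant of these cytokines, with 5769 ± 492 CPM in WT and 3728 ± 1393 CPM in K256R, and did not pass (log2 difference -0.70, adjusted p = 0.197 in limma). Of the 11 RORγt-dependent Th17 genes, 2 fell and 9 did not pass, and 7 were lower when adjusted over the list alone. The list was lower in K256R by camera (adjusted p = 8.9e-05; adjusted p = 0.453 with an estimated correlation). Of the 14 Th17 cytokines and receptors, 2 fell and 12 did not pass, and adjusted over the list alone 3 were lower and 1 higher. That list did not pass camera (adjusted p = 0.0529), but it did without WT replicate 1 (adjusted p = 0.0176), K256R replicate 2 (adjusted p = 0.0334) or K256R replicate 3 (adjusted p = 0.0296), and without the filter (adjusted p = 0.0391).

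**Figure D1:**
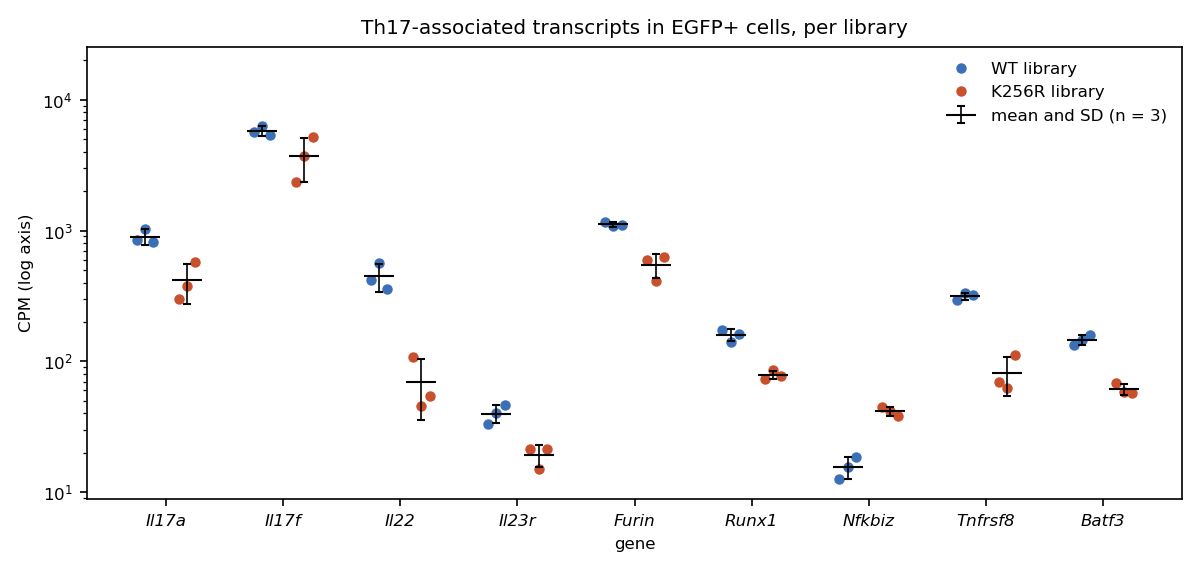
CPM of 9 genes on a log axis, with 1 point per library, WT in blue and K256R in red, and the mean and SD of each group (n = 3) in black. Il22 lies at 355 CPM or above in WT and at 108 CPM or below in K256R.

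Among 12 Th17 transcription factors, Runx1 fell and Nfkbiz rose, and the other 10 did not pass. The same counts, 1 lower and 1 higher, were obtained when adjusted over the list alone. Runx1 went from 159 ± 16.7 to 78.9 ± 6.17 CPM, and Nfkbiz, which encodes the nuclear IκBζ protein, from 15.7 ± 2.97 to 41.6 ± 3.54 CPM (SD, n = 3). Batf (81.0 against 64.9 CPM), Irf4 (999 against 1100 CPM), Maf (610 against 558 CPM), Ahr (272 CPM in both), Stat3 (967 against 880 CPM) and Rora (375 against 304 CPM) did not pass. The list did not pass camera (adjusted p = 0.342). Of 13 tested genes of the pathogenic Th17 list, Il22 and Il23r fell, Gzmb rose from 1.16 ± 0.237 to 5.25 ± 1.23 CPM and 10 did not pass, and adjusted over the list alone 3 were higher and 3 lower. Gzmb encodes a cytotoxic granule protease. It lost its call in 7 of 13 settings, in limma without any 1 WT library (adjusted p of 0.133 to 0.153), without K256R replicate 2 (adjusted p = 0.0569) or K256R replicate 3 (adjusted p = 0.0556), with the replicate number as a block (adjusted p = 0.0541) and with voom (adjusted p = 0.0505). That list did not pass camera (adjusted p = 0.342). None of the 8 non-pathogenic Th17 genes passed, and 1 was lower when adjusted over the list alone, although the list was lower by camera (adjusted p = 0.02996; adjusted p = 0.507 with an estimated correlation). Il9 had a log2 difference of -3.64 (adjusted p = 0.0989) and Il10 of -2.10 (adjusted p = 0.166). In limma without K256R replicate 1, Il9 (-4.83, adjusted p = 0.000159) and Lgals3 of the pathogenic list (-3.48, adjusted p = 0.000332) passed. Without any other library they did not, with log2 differences as small as -2.89 for Il9 (adjusted p of 0.19 to 0.288) and -1.82 for Lgals3 (adjusted p of 0.347 to 0.431). Il10 did not pass in any fit without 1 library (adjusted p of 0.0622 to 0.412 in limma), and its log2 difference was -1.36 without K256R replicate 2 (adjusted p = 0.257).

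Over all tested genes, 152 of 13224 changed, with 98 higher and 54 lower in K256R. Of these, 59 were at least 2-fold higher and 38 at least 2-fold lower. After Il22, the largest falls among genes with a mean of at least 5 CPM were those of Loxl2, a lysyl oxidase family member (13.0 ± 1.73 to 1.58 ± 0.581 CPM), Plcd1, Pdgfa, Tnfrsf8, Coch, Mpzl2, Sphk1, Jcad, Cavin1, Lhx6 and Antxr1, with log2 differences from -2.45 to -1.87. As a ratio of mean CPM the fall of Loxl2 (8.19-fold) was larger than that of Il22 (6.41-fold). Tnfrsf8, which encodes CD30, fell from 315 ± 18.6 to 80.9 ± 26.6 CPM, Jcad from 88.9 ± 14.7 to 23.1 ± 4.30 CPM, and Pdgfa, a platelet-derived growth factor chain, from 30.8 ± 7.69 to 6.65 ± 0.136 CPM (SD, n = 3). The metallothionein genes Mt1 (602 ± 46.1 to 290 ± 6.47 CPM) and Mt2 (311 ± 23.4 to 145 ± 6.15 CPM), chosen after their values were seen, also fell.

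The largest rises described here were those of Gpnmb, Lbp, Scml4, Pik3ip1, Cmah, Dzip1, Psrc1, Ypel2, Arhgef3, Lsp1 and Slc16a10, with log2 differences from 2.51 down to 1.47. Pik3ip1, an inhibitor of PI3 kinase, rose from 13.9 ± 2.23 to 52.8 ± 16.8 CPM, and Psrc1 from 31.7 ± 5.36 to 110 ± 41.4 CPM. Slc16a10, a transporter of aromatic amino acids, rose from 12.4 ± 1.03 to 36.2 ± 1.49 CPM (SD, n = 3), with an SE of 0.14 on the log2 scale. With a pseudocount of 0.1 the log2 difference of Gpnmb was 3.27 (adjusted p = 0.0194 in limma). Ypel2 lost its call in 12 of 14 settings (adjusted p of 0.0529 to 0.183 in limma), among them median-of-ratios scaling (adjusted p = 0.0684), and Psrc1 lost its call in 7.

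**Figure D2:**
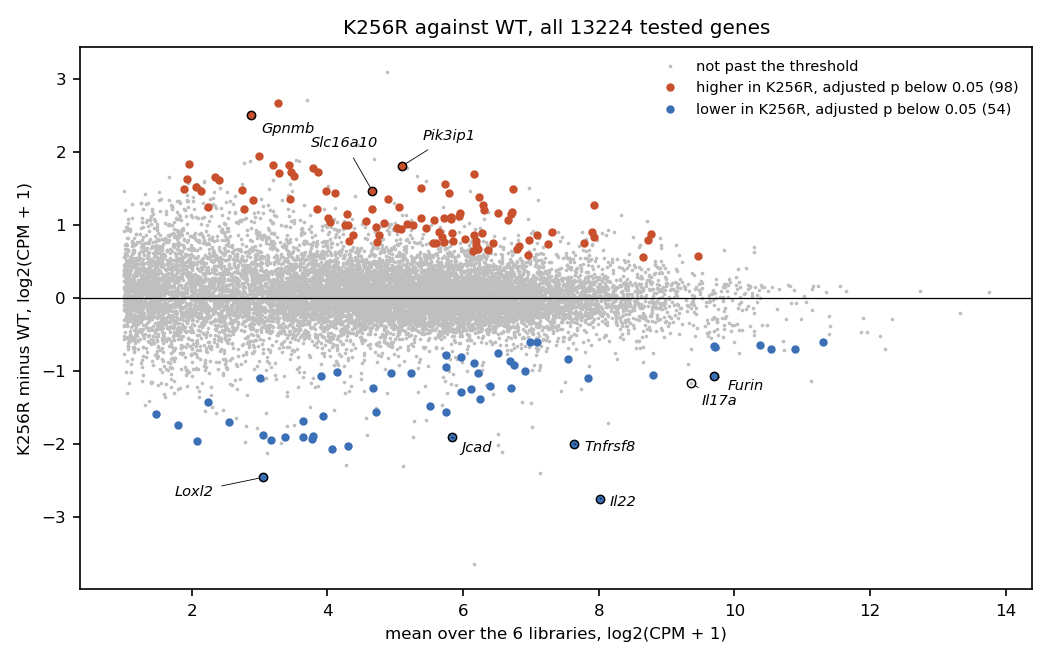
Difference between genotypes (K256R minus WT, log2(CPM + 1), vertical axis) against mean level (log2(CPM + 1) over the 6 libraries, horizontal axis) for 13224 genes. The 98 genes that rose are in red and the 54 that fell in blue; labelled genes are circled, and Il17a (-1.16) is not past the threshold.

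These calls came from limma with 3 libraries per group, and 2346 genes had an unadjusted p below 0.05. No gene passed in limma without WT replicate 2 or without WT replicate 3 (1600 and 1615 genes at an unadjusted p below 0.05), and 3 passed without WT replicate 1, whereas 1849 passed without K256R replicate 1. With median-of-ratios scaling 59 genes were higher and 55 lower, and with trends on GC content and transcript length removed 69 were higher and 71 lower. The called genes that these fits tested (152, or 150 with GC and length trends removed) all kept their direction. The groups of all 152 did not overlap, as for 24.4% of all tested genes, so leaving out a library could not turn a direction.

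Naive and memory genes were higher in K256R as a list (camera adjusted p = 0.00555; adjusted p = 0.453 with an estimated correlation). Of its 9 tested members, 2 rose, among them Lef1, 7 did not pass, and 5 were higher when adjusted over the list alone. Lef1, a transcription factor of naive T cells, rose from 108 ± 4.99 to 207 ± 35.8 CPM. Ccr7 (207 ± 44.9 against 327 ± 74.6 CPM) and Il7r (148 ± 3.73 against 189 ± 18.0 CPM) did not pass over all genes. Btla, an inhibitory receptor, rose from 54.7 ± 5.78 to 126 ± 24.1 CPM and was the 1 member past the threshold of both the Tfh list (10 tested, camera adjusted p = 0.191) and the co-inhibitory receptor list (6 tested, camera adjusted p = 0.181). Egr1, an immediate early gene, was the 1 of 14 activation genes that rose (33.9 ± 5.19 to 64.8 ± 11.05 CPM; camera adjusted p = 0.701). It lost its call in 9 of 14 settings, among them median-of-ratios scaling (adjusted p = 0.0596 in limma), each fit without 1 WT library (adjusted p of 0.167 to 0.201) and that without K256R replicate 2 (adjusted p = 0.0961). Batf3 was the 1 of 11 AP-1 and related factors that fell (145 ± 12.7 to 61.3 ± 6.10 CPM; camera adjusted p = 0.191). Ccr8 was the 1 of 7 tested Th2 genes that fell (64.8 ± 7.27 to 24.1 ± 10.3 CPM; camera adjusted p = 0.202, or 0.00581 at a minimum of 5 CPM). That minimum leaves out Gata3, Il4 and Il13, the Th2 genes with positive differences. The co-inhibitory list passed camera without WT replicate 3 (adjusted p = 0.0309). Adjusted over the list alone, 1 Tfh gene, 1 co-inhibitory receptor and 2 activation genes were higher, and 1 activation gene, 1 AP-1 factor and 2 Th2 genes were lower.

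Mitochondrially encoded and glycolysis transcripts were lower in K256R as lists. The 13 mitochondrially encoded genes all had negative differences (mean -0.53, camera adjusted p = 5.4e-07; adjusted p = 0.507 with an estimated correlation), though none passed alone over all genes and 8 were lower when adjusted over the list alone. All entries of the mitochondrial chromosome together took 1.96, 2.57 and 2.75% of the CPM in WT replicates 1 to 3 and 1.95, 1.90 and 1.73% in K256R replicates 1 to 3. By that total WT replicate 1 lay beside K256R replicate 1. Of the 13 listed genes, WT replicate 1 lay above every K256R library for 8 and below for 0. K256R replicate 1 lay below every WT library for 8 and above for 0. The least p-values were those of mt-Nd5 (1348 ± 267 against 799 ± 148 CPM) and mt-Cytb (2088 ± 277 against 1297 ± 278 CPM). Of 20 glycolysis genes, Eno1, Tpi1 and Ldha fell, 17 did not pass and 8 were lower when adjusted over the list alone (camera adjusted p = 2.7e-06; adjusted p = 0.507 with an estimated correlation). K256R replicates 1 and 3 lay below every WT library for 17 and 16 of the 20 and above for 1 each. K256R replicate 2 lay below for 9 and above for 5. Ldha, which encodes a lactate dehydrogenase subunit, fell from 3032 ± 136 to 2015 ± 140 CPM and Tpi1 from 1618 ± 120 to 1040 ± 32.9 CPM, with calls lost in 7 and 6 of 14 settings. Eno1 (2345 ± 49.2 to 1453 ± 40.4 CPM) has a near-identical copy, Eno1b, and how reads were divided between them is not given in the sources used here, so its level is uncertain. Nuclear-encoded respiratory chain genes did not pass camera (44 tested, adjusted p = 0.0913), nor did TCA cycle (adjusted p = 0.701), fatty acid oxidation (adjusted p = 0.596), fatty acid synthesis (adjusted p = 0.186), cholesterol biosynthesis (adjusted p = 0.551), amino acid transporter (adjusted p = 0.701) or hypoxia response genes (adjusted p = 0.0563), and no member of these lists passed over all genes. Adjusted over the list alone, 3 hypoxia genes were lower and 1 amino acid transporter was higher. By camera the hypoxia list passed without WT replicate 2 (adjusted p = 0.00762) or K256R replicate 2 (adjusted p = 3.7e-06), fatty acid synthesis without K256R replicate 2 (adjusted p = 0.00313), and the nuclear-encoded respiratory chain with median-of-ratios scaling (adjusted p = 0.0339).

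The ER stress, heat shock, histone and interferon response lists were lower by camera at the preset correlation. Of 16 ER stress and ATF4 response genes, Trib3, a pseudokinase, fell from 22.5 ± 2.13 to 10.8 ± 2.29 CPM with a call lost in 8 of 14 settings, and 15 did not pass (camera adjusted p = 0.0178; adjusted p = 0.507 with an estimated correlation). No member passed over all genes among 9 heat shock genes (camera adjusted p = 0.00352; adjusted p = 0.507 with an estimated correlation), 9 replication-dependent histones (camera adjusted p = 0.0401; adjusted p = 0.665 with an estimated correlation) and 13 interferon response genes (camera adjusted p = 0.0416; adjusted p = 0.674 with an estimated correlation). Adjusted over the list alone, 1 ER stress gene and 3 heat shock genes were lower, and no histone or interferon gene passed. K256R replicate 1 stood apart in heat shock and interferon genes. In the heat shock list it lay above every WT library for 4 of the 9 genes and below every WT library for 3, whereas K256R replicates 2 and 3 lay below every WT library for 7 and 9. In the interferon list K256R replicate 1 lay above every WT library for 10 of the 13 genes, whereas K256R replicates 2 and 3 lay below every WT library for 11 and 10. The mean of that list was -0.54, -1.001 without K256R replicate 1 (camera adjusted p = 7.19e-05) and -0.25 without K256R replicate 2, and the list did not pass without WT replicate 1 (adjusted p = 0.0631) or WT replicate 2 (adjusted p = 0.122). Hspa1a stood at 32.1 ± 11.5 CPM in WT and 12.5 ± 3.72 CPM in K256R, and Hspa1b at 29.8 ± 10.6 and 13.5 ± 1.35 CPM. All of these lists lost their call without K256R replicate 3, with adjusted p by camera of 0.0554 for ER stress, 0.0623 for heat shock, 0.0513 for histones and 0.266 for interferon response. With median-of-ratios scaling the histones (adjusted p = 0.0611) and the interferon response (adjusted p = 0.0623) did not pass, and without K256R replicate 2 they did not either (adjusted p = 0.152 and 0.242).

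**Figure D3:**
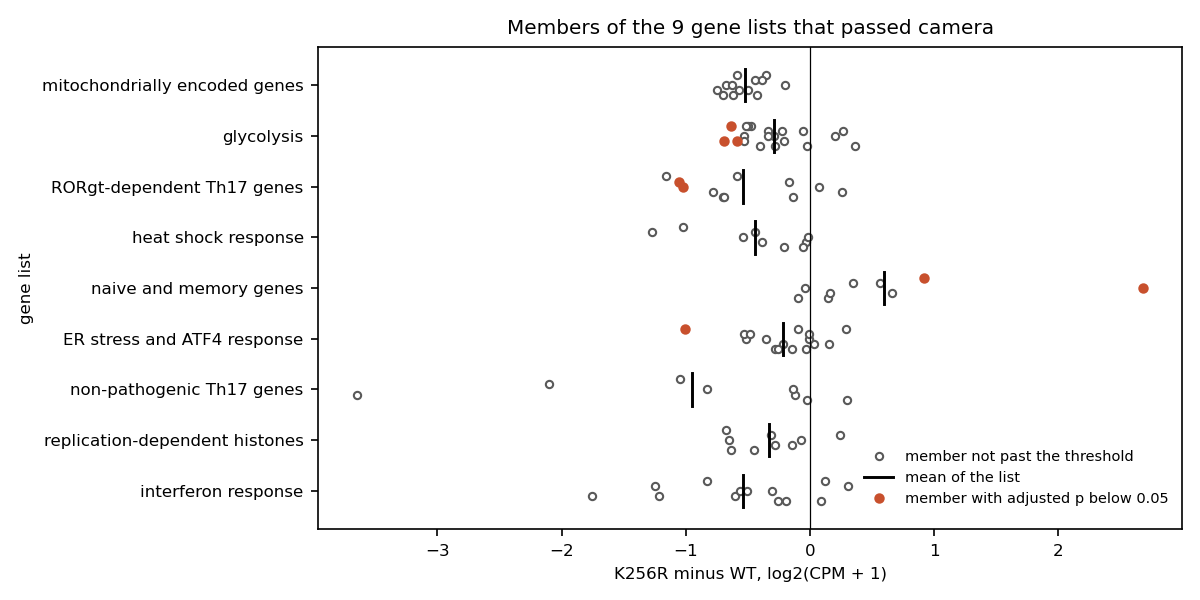
Differences between genotypes (K256R minus WT, log2(CPM + 1), horizontal axis) of the tested members of the 9 gene lists that passed camera at the preset correlation. Filled points are members past the threshold over all genes, open points are the others, and the black bar is the mean of the list; all 13 mitochondrially encoded genes lie below 0.

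No gene of the Treg (12 tested, adjusted p = 0.738), Th1 (10 tested, adjusted p = 0.606), migration receptor and integrin (16 tested, adjusted p = 0.677), cell cycle (25 tested, adjusted p = 0.224), apoptosis (12 tested, adjusted p = 0.203) or circadian clock lists (15 tested, adjusted p = 0.435) passed, and none of these lists passed camera. The cell cycle list was lower by camera without K256R replicate 1 (adjusted p = 0.000156), with a mean of 0.132 without K256R replicate 2. K256R replicate 1 lay above every WT library for 21 of the 25 cell cycle genes, and K256R replicate 2 below every WT library for 23. Apoptosis regulators were higher without K256R replicate 3 (adjusted p = 0.0373). Adjusted over the list alone, 4 migration receptors, 2 apoptosis regulators, 1 Treg, 1 Th1 and 1 clock gene were higher, and 2 migration receptors, 1 Treg and 1 Th1 gene were lower. For the Th2, activation and TCA cycle lists camera gave a lower direction while their means were 0.10, 0.00024 and 0.02. Camera compares the test statistics of the members with those of all other tested genes, so its direction can differ from the sign of the mean. The mean of the Th2 genes was -0.412 without K256R replicate 1, the library high in Il4 and Il13. It was -0.645 at a minimum of 5 CPM, which leaves out the 3 members with positive differences (Gata3, Il4 and Il13). For amino acid transporters the median was 0.08 with a mean of -0.001. In all, 8 of the 30 lists were lower and 1 higher, and none passed with an estimated correlation or with fry's test for a change in 1 direction. With fry's test for change in either direction 14 lists passed.

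Markers of other cells were measured in the same libraries. Camera on these marker lists was not planned, and its p-values were adjusted over the marker lists alone. T cell identity genes were higher in K256R (12 tested, camera adjusted p = 0.0115; adjusted p = 0.212 with an estimated correlation), with a rise of Cd5 from 306 ± 25.5 to 568 ± 67.3 CPM and 11 members not passing. Of 5 tested NK and cytotoxic cell markers, Klrk1, which encodes NKG2D, fell from 21.8 ± 1.20 to 6.74 ± 2.77 CPM (camera adjusted p = 0.0913). No B cell (5 tested), CD8 T cell (1 tested), myeloid (1 tested) or platelet (1 tested) marker passed, and no erythroid or dendritic cell marker reached a mean of 1 CPM. Adjusted over the list alone, 3 T cell identity, 2 B cell and 1 myeloid marker were higher, and 1 T cell identity, 2 B cell and 2 NK and cytotoxic cell markers were lower. The B cell list did not pass camera (adjusted p = 0.908). Xist stood at 801 to 1109 CPM in WT and 1214 to 1853 CPM in K256R and did not pass (adjusted p = 0.0852); the Y-linked genes of the list were not analysed here.

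The WT libraries were more alike than the K256R libraries. K256R replicate 1 had a mean correlation across genes of 0.960 with its own group and of 0.972 with WT, and held transcripts of the innate-like T cell list (Zbtb16 and Trgc1) and of the Th2 list (Il4 and Il13) that were scarce elsewhere; Il4 and Il13 were chosen after their values were seen. Zbtb16, which encodes PLZF, was at 20.7 CPM in K256R replicate 1 and at most 0.309 CPM in the other 5 libraries, Il4 at 18.1 CPM against at most 0.185 CPM, Il13 at 12.7 CPM against at most 0.803 CPM and Trgc1 at 5.74 CPM against at most 0.432 CPM. In all, 122 genes were at least 3 times higher in K256R replicate 1 than in any other library. Chst2 and Dsp, chosen after their values were seen and on none of the lists, were among them. The counts were 74 for K256R replicate 2, 41 for K256R replicate 3 and 15 to 22 for WT libraries. None of the 3 tested markers of gamma-delta and innate-like T cells passed between genotypes (camera adjusted p = 0.181).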

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

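The voom weights and the removal of GC content and length trends were chosen after the data had been seen. The count models planned for recovered whole reads were not run, since 78.4 to 80.1% of low values per library were whole. All 152 called genes that a setting tested kept their direction in all 14 settings, but the number of calls moved. The groups of these 152 did not overlap, so leaving out a library could not have turned a direction. Median-of-ratios scaling gave 59 higher and 55 lower genes. eBayes without trend or robust options gave 41 genes (23 higher, 18 lower), of which 37 were among the 152. Voom gave 99 (55 higher, 44 lower), 97 of them shared. Removal of GC and length trends gave 140 (69 higher, 71 lower), 112 shared. A pseudocount of 0.1 gave 152, no filter 188 and a minimum of 5 CPM 141. Without 1 library, counts ranged from 0 to 1849 in total, from 0 to 1004 for higher and from 0 to 845 for lower genes. The lowest came without WT replicate 2 or WT replicate 3 and the highest without K256R replicate 1; 113 genes passed without K256R replicate 2 (60 higher) and 109 without K256R replicate 3 (65 higher). The cause was not tested. Il22 lost its call in the 3 fits without a WT library (adjusted p 0.0773 to 0.117 in limma; 0.000332 to 0.0401 without a K256R library), and Ypel2 kept its call in 2 of 14 settings, Egr1 and Gimap6 in 5, Il23r, Trib3 and Trp53inp1 in 6, Psrc1 and Ldha in 7, and Gzmb in 6 of 13. Voom moved Gpnmb to 3.33 (adjusted p = 0.0862), Gzmb to 2.14 (0.0505) and Loxl2 to -3.04 (0.0191).

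With the replicate number as a block, 96 genes passed (57 higher, 39 lower), 78 of them among the 152, and the Th17 cytokine and receptor list passed (adjusted p = 0.048). The values gave no sign that the numbers pair the samples. Deviations of same-numbered libraries correlated at -0.012, -0.165 and -0.009. Each WT library matched a K256R library of another number best, though only at 0.071, 0.181 and 0.209. With 3 libraries per group these correlations cannot decide whether same-numbered libraries were handled together.

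Of the 9 gene lists called at the preset correlation (8 lower, 1 higher), 0 passed with an estimated correlation, 0 lower and 0 higher (2 of 30 at an unadjusted p below 0.05), and 0 with fry for a change in 1 direction, 0 lower and 0 higher (5 at an unadjusted p below 0.05). Without 1 library, 5 to 9 lists were lower and 1 to 2 higher. Directions turned only among values not past the threshold in the main test, and the cause was not tested. With fry the activation list (mean 0.000), TCA cycle (0.017) and amino acid transporters (-0.001) took the other direction, as did Th1 genes (0.099) at a minimum of 5 CPM. That minimum leaves out Ccl5 and Hlx of the Th1 list, both with negative differences. Over the fits without 1 library, means ranged from -0.412 to 0.37 for Th2, -0.048 to 0.027 for amino acid transporters, -0.004 to 0.301 for Treg, -0.094 to 0.012 for Th1, -0.152 to 0.135 for activation, 0.005 to 0.039 for TCA cycle, -0.039 to 0.034 for fatty acid oxidation, -0.028 to 0.203 for cholesterol biosynthesis and -0.349 to 0.132 for cell cycle genes. Interferon response lost its call in 7 of 14 settings with camera at the preset correlation and histones in 5 of 13; too few histones had GC values for that setting. Single genes ranged from -0.205 to 0.107 for Ahr, -0.312 to 0.078 for Stat3, -0.045 to 0.417 for Ccr6, -0.228 to 1.66 for Il13 and -0.159 to 1.22 for Trgc1. Differences in genes near the floor of 3 reads (0.1495 to 0.1899 CPM) are limited by depth.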

Other observations

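The gene lists in the next paragraph and the genes named from them, the tests of dilution, the test of a mixed-up library and the test of the share of each difference left after GC and length correction were chosen only after the data had been seen.

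Genes that restrain T cell receptor signalling were higher in K256R. Of 16 such genes, Pik3ip1, Dgka, Btla, Cd5 and Cd6 rose, 11 did not pass, and 15 had positive differences, with a camera adjusted p of 3.5e-08 (adjusted p = 0.0231 with an estimated correlation). Dgka, a diacylglycerol kinase, rose from 172 ± 8.14 to 311 ± 31.0 CPM and Cd6 from 308 ± 18.1 to 537 ± 37.0 CPM (SD, n = 3). All lists of this paragraph were written after the called genes had been seen, and members of the T cell receptor, FoxO, GIMAP and YPEL lists were among those genes, so their p-values are not independent evidence of direction. Of 18 tested FoxO targets, 5 rose, among them Pik3ip1 and Trp53inp1 (161 ± 12.4 to 275 ± 45.6 CPM), and 16 had positive differences (camera adjusted p = 8.8e-07; adjusted p = 0.0832 with an estimated correlation). All 8 GIMAP genes, which encode lymphocyte GTPases, had positive differences and Gimap6 rose from 140 ± 28.0 to 347 ± 95.5 CPM (camera adjusted p = 0.000678; adjusted p = 0.0971 with an estimated correlation). All 5 YPEL genes had positive differences and 2 rose, Ypel3 and, in the main test but only 2 of 14 other settings, Ypel2 (camera adjusted p = 0.00221; adjusted p = 0.151 with an estimated correlation). Cytosolic ribosomal protein genes were higher by a mean of 0.13 over 76 genes (camera adjusted p = 0.000980; adjusted p = 0.495 with an estimated correlation), 0.09 with median-of-ratios scaling, and none passed alone. K256R replicate 1 lay above every WT library for 21 of the 76 and below for 15. K256R replicates 2 and 3 lay above for 60 and 49 and below for 2 and 3. Nuclear long non-coding RNAs did not pass camera as a list (8 tested, adjusted p = 0.0554), and 4 were higher when adjusted over the list alone. The directions held with median-of-ratios scaling and without K256R replicate 1. When GC and length trends were removed Gimap6 lost its call with a similar log2 difference and a larger SE (1.28, SE 0.231, to 1.24, SE 0.261; adjusted p = 0.0707, range over all settings 0.00146 to 0.189). Trp53inp1 lost its call with a smaller one (0.76, SE 0.14, to 0.61, SE 0.119; adjusted p = 0.0562, range 0.0105 to 0.204), and Gimap6 also did with median-of-ratios scaling (adjusted p = 0.0722). In limma none of the genes named here passed when any 1 WT library was left out.

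For the 152 called genes, 10 splits of the 6 libraries into 3 and 3 are too few for a share under 0.05; the real split, 1 of the 10, gave 152 and the highest of the others 0. A smooth trend of each library on GC content or transcript length was not the whole of these differences. After the trends were removed a median of 97.1% of the log2 difference of the 150 called genes with values was left (5th percentile 82%), and all 150 kept their sign. This measure was chosen after the preset one left the question open, and it does not cover bias that follows no such trend. Whether such trends added to single calls stays open, since 74.7% of the 150 (112) remained called, between the bounds of 50% and 80% set in advance. The balance of calls moved from 98 higher and 54 lower to 69 and 71, and a median of 94.6% was left among the higher and 101% among the lower genes.

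The innate-like transcripts of K256R replicate 1 may come from innate-like T cells among the sorted cells. In a second list written before its values were seen, 1 of 12 measured members, Trav11, was at least 3 times higher there than in any other library (3.02 CPM against at most 0.0848 CPM). This exceeded 84.2% of 10000 random lists matched on mean expression, short of the 95% set in advance, so innate-like T cells cannot be told apart from another origin. Trbv1, chosen after its value was seen, stood at 65.2 CPM against at most 11.2 CPM; Trav11 with Trbv1 is one of the receptor pairings of invariant NKT cells. Whether K256R replicate 1 was a WT library under a K256R label stays open. Of the 1849 genes that best separated WT from the other 2 K256R libraries, 36.0% lay nearer to K256R in replicate 1. Left-out libraries treated in the same way gave 12 to 16.6% for WT and 66.7 to 71.6% for the other K256R libraries. A plain bound of 50%, used at first, would have favoured a mixed-up label, since 64.0% lay nearer to WT, but left-out WT libraries gave 83.4 to 88.0%. The bound that replaced it was set after these values were seen. The WT libraries were more alike than the K256R libraries, so an unusual WT library could also exceed their range. A library holding cells of both genotypes was not tested and stays open.

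Lower Th17 cytokine transcripts in K256R might reflect dilution by cells without the Th17 programme, although all cells were sorted for the reporter. Against this as the sole cause for Il17a, Il17a differed by a further -0.46 (SE 0.0993) on the log2 scale from Il17f. That comparison was set after both differences had been seen, and its SE does not allow for the choice. Il22 differed from Il17f by a further -2.04 (SE 0.677). The fall of Il22 was the largest among called genes on that scale, so this gap follows from its choice and does not bear on dilution. Dilution in part, and for Il17f, stays open. Diluting cells that express Il17f would escape this test. With GC and length trends removed Il22 differed by -2.76 (SE 0.276, adjusted p = 0.0137; 0.000332 to 0.117 over all settings).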
